A study of Homo sapiens with 34 samples.

How the data were processed

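RNA was measured with single-color Affymetrix arrays in MCF7/BUS, a stock of the established human breast adenocarcinoma cell line MCF7. Biotin-labelled cRNA was made from 6 µg of total RNA per array, per the labels' protocols. The 34 arrays fall into 8 groups by their titles and characteristics. In the estradiol experiment, 5 arrays each hold cells given 0, 10, 30, 60 or 100 pM 17beta-estradiol (E2). In the starvation experiment, 3 arrays each hold cells kept for 0, 1 or 2 days in medium with stripped serum. The titles call the arrays of a group biological replicates, and the series' design text says that each experiment was repeated independently. No array was left out, and the values of no 2 arrays were identical.

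The values deposited by the authors are linear signal intensities, 1 per probe set and array, made with MAS5, per the submitters' processing notes. The MAS5 version and the scaling target are not given in the sources used here. The 2% trimmed mean of the signal was 500.2 on every array, with a spread between arrays of 0.0091%, so the intensities were used without further normalization. Because every array was scaled to that mean, a change in the total amount of mRNA per cell would not be visible, and fold changes are relative to the bulk of the probe sets. The median log2 change of all genes stayed between -0.045 and 0.0902 in every comparison.

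Of the 22283 probe sets, 68 are control probe sets and stayed out of every test. In the platform's annotation table, 19065 of the others are paired with 1 gene symbol, 1043 with several and 2107 are unnamed there. Only probe sets with 1 symbol were used, and of several probe sets of a gene the one with the highest mean log2 value over all arrays stood for it, which gave 11963 genes, 4310 of them with several probe sets. Of the identifiers in that table, 99.94% matched a reference gene table, and no symbol needed an update. No genome coordinates were used.

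Signals were transformed as log2(signal + 33.6), where 33.6 is the 20th percentile of all values. Fold changes are on that scale and understate the change of dim genes. Each experiment was fitted on its own with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes), the 25 estradiol arrays in one fit and the 9 starvation arrays in another. P-values were adjusted by Benjamini-Hochberg within each comparison, and a gene was counted as changed at an adjusted p under 0.05. Each dose was compared with 0 pM, 30 with 10, 60 with 30, 100 with 60 and 100 with 10 pM, and a moderated F test covered all 5 doses. Day 1 and day 2 were compared with day 0 and with each other. Unless another test is named, adjusted p-values of genes are limma's.

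The groups compared, the tests, the rule for named genes, the gene lists and most alternatives were set before the data were examined. In the comparisons of 100 with 0 pM and of day 2 with day 0, the named genes are the 10 largest rises and 10 largest falls past the test, without overlap between the arrays of both groups and with a mean signal in the higher group above the table's median of 177.9. The other comparisons have the 5 largest each way. Up to 4 members past the test were named for each gene list, with 10 genes in every comparison (ESR1, PGR, TFF1, GREB1, MYC, CCND1, CXCL12, IGFBP4, MKI67 and TOP2A). For the overlap of both experiments, the 10 genes were named whose smaller change was largest. A gene named outside this rule is said to have been chosen after its values were seen.

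The 19 gene lists hold 428 genes, of which 380 were measured. They cover known estrogen-induced and estrogen-repressed genes, DNA replication, mitosis, cholesterol synthesis and uptake, hypoxia and glycolysis, the unfolded protein response, the interferon response, p53 targets, ribosome biogenesis, FOXO and quiescence genes, immediate early genes, luminal epithelial identity, basal epithelial markers, fibroblast and endothelial markers, immune cell markers, steroid receptors and coregulators, the insulin-like growth factor pathway and apoptosis regulators. Each list was tested against the other genes with camera at its preset correlation of 0.01, adjusted over the lists of a comparison. The same test with a correlation estimated from the data was run beside it, as was fry, which tests whether a list's genes move one way without comparing them with other genes. The median, the mean and the test of a called list had the same sign, and they differed in sign only in lists that were not called. These were p53 targets, steroid receptors, insulin-like growth factor genes and apoptosis regulators at 10 pM, hypoxia, apoptosis, receptor and growth factor genes at 30 pM, interferon, fibroblast and apoptosis genes at 60 pM, interferon genes at 100 pM, basal markers on day 1, and cholesterol, immediate early and fibroblast genes on day 2.

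The response share of a dose is the median over genes of its log2 change divided by that at 100 pM. It was taken over genes past the F test with a mean log2 change over 60 and 100 pM of at least 1 in size. For the mean ± SD, each array was set against the mean of the 0 pM arrays. The 3 comparisons of induced with repressed genes used exact two-sided sign-flip tests over the 5 replicate numbers, whose smallest possible p is 0.0625.

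Each result was recomputed with quantile normalization, with scaling to a common 2% trimmed mean, with pseudocounts at the 5th and 40th percentiles (9 and 114.2), with a filter on dim genes, with the mean of a gene's probe sets, with every probe set by itself, with the replicate number as a block, with all 34 arrays in one fit, with only the groups compared, with trend and robust variance settings, with array weights, and without each array in turn. Response shares were also recomputed with genes chosen on replicates 1 to 3, with separate 0 pM arrays and with a minimum log2 change of 0.5. After the data were seen, 3 alternatives were added on RNA integrity, read from the signal ratio of the 3' and 5' probe sets for beta-actin. They leave out arrays with a ratio above 2 (3 arrays), leave out those above 1.5 (5 arrays), or take the log2 ratio as a covariate. As an exception, response shares were not run with only the groups compared, trend and robust settings, array weights, single probe sets or this covariate. The F test was not run with only the groups compared.

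The calculations were tested on simulated data with the spread of the real arrays, with 100 genes changed at each size. The changed genes were drawn from those with a mean log2 value above log2 of the table's median signal of 177.9. Noise was drawn independently for each gene and array, while deviations of the real arrays were correlated. The recovery therefore does not cover dim genes or shared deviations. For 100 against 0 pM, 93 of 100 genes with a true log2 change of 1 and 100 of 100 with a change of 2 were recovered, among 219 calls of which 14 were unchanged genes. For day 2 against day 0, 55 and 93 of 100 were recovered, among 159 calls of which 7 were unchanged genes. Calls that were neither recovered nor unchanged genes belonged in both cases to a list given a smaller change to test camera. Simulated response shares of 40% were estimated at 39.7% to 41.5%. Plots were drawn with matplotlib 3.10.9.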

Results

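Expression was measured in MCF7/BUS, a stock of the MCF7 breast adenocarcinoma line, whose cells carry the estrogen receptor. In the estradiol experiment, cells attached for 16 hours in phenol red-free medium with 5% stripped serum, were washed, and then received 0, 10, 30, 60 or 100 pM 17beta-estradiol (E2), the main natural estrogen, for 48 hours, with 5 arrays per dose. In the starvation experiment, cells were kept in medium with stripped serum, which holds little steroid hormone, for 0, 1 or 2 days, with 3 arrays per day. Median signals of the 34 arrays lay between 155.8 and 206.4. Correlations between arrays of one group lay between 0.932 and 0.979. The signal ratio of the 3' to the 5' beta-actin probe sets, which rises when RNA is degraded, was 2.87 in 10 pM replicate 3, 2.60 in 100 pM replicate 3, 2.96 in day 2 replicate 2 and 1.95 in day 2 replicate 3. On all other arrays it was 1.504 or lower. The number of arrays limits the precision of every value.

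The comparison of 100 pM with 0 pM addressed which genes respond to added estrogen. Many known estrogen-induced genes and most genes of the mitosis and DNA replication lists were higher at 100 pM, while many known estrogen-repressed genes were lower. Among the largest rises, PDZK1, which encodes a scaffold protein, rose from a signal of 241 ± 50.7 to 2139 ± 238 (SD, n = 5 each), a log2 change of 3.00 ± 0.17 (SE, adjusted p = 6.37e-11). CCN5, which encodes a secreted matrix-associated protein, rose 13.0-fold, from 216 ± 224 to 2229 ± 585 (adjusted p = 2.28e-06). FHL2 rose 7.80-fold, MYBL1 7.62-fold, MGP 6.88-fold, PRSS23 6.57-fold, OLFM1 5.73-fold, NCAPH 5.71-fold, NUDT1 5.40-fold and CDC45 5.12-fold. The largest fall was in BIK, a gene that promotes apoptosis, from 430 ± 96.5 to 21.7 ± 4.22 (log2 change -3.05 ± 0.25 SE, adjusted p = 2.06e-08). CSTA fell 6.10-fold, APOD 5.22-fold, PRKCD 5.13-fold, PSCA 4.98-fold, SIL1 4.96-fold, TNS3 4.90-fold, IL1R1 4.61-fold, IFT122 4.47-fold and TNFSF10 4.47-fold. In all, 1464 of 11963 genes changed, 772 up and 692 down, and 386 of them changed by 2-fold or more. With the replicate number as a block the count was 2067, and without any single array it was between 1226 and 1456.

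Several classical targets were followed at every dose. PGR, the progesterone receptor gene, rose from 96.1 ± 29.2 to 458 ± 122 at 100 pM (log2 change 1.92 ± 0.21 SE, adjusted p = 8.42e-07). GREB1 rose 3.30-fold, IGFBP4 2.63-fold, TFF1 2.20-fold and the cyclin gene CCND1 1.90-fold. Of GREB1's 2 other probe sets, 1 also rose and 1 had the opposite sign. The proliferation markers TOP2A and MKI67 rose 3.59-fold and 1.77-fold. ESR1, the gene of the estrogen receptor itself, fell from 7145 ± 1774 to 3469 ± 747 (log2 change -1.03 ± 0.21 SE, adjusted p = 0.00158). Of its 8 other probe sets, 2 also fell and 1 had the opposite sign. MYC had a log2 change of -0.32 ± 0.23 (SE, adjusted p = 0.447) and CXCL12 one of 0.33 ± 0.24 (SE, adjusted p = 0.444), which did not exceed the spread between replicates.

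**Figure D1:**
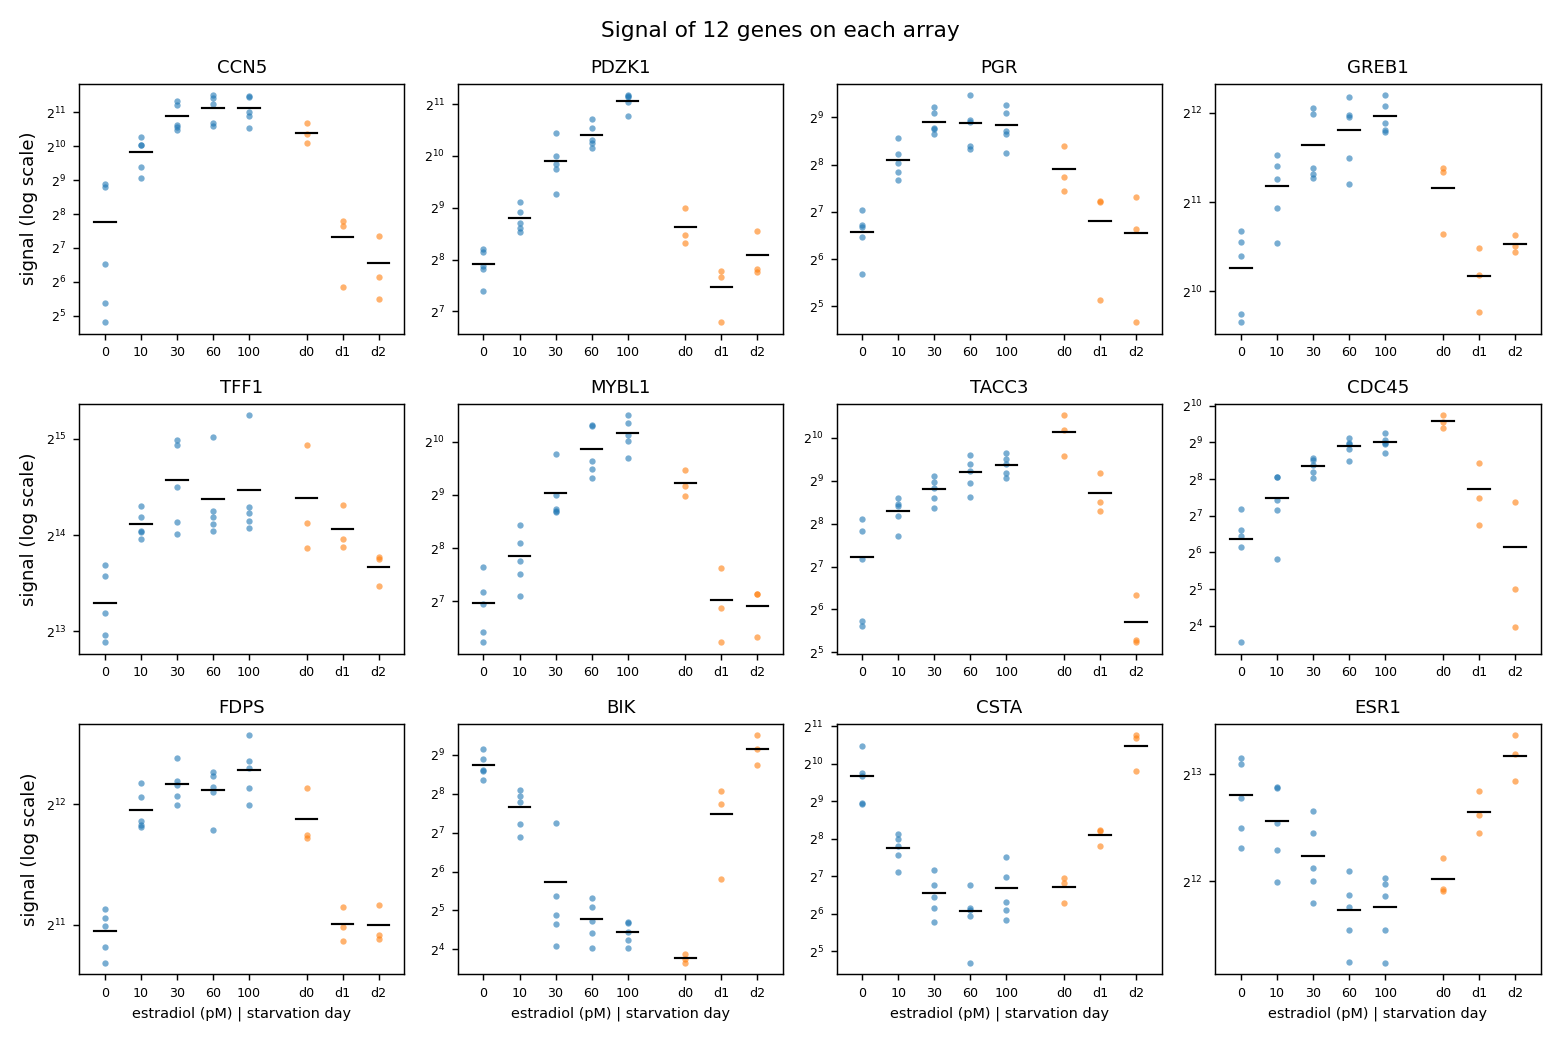
Signals of 12 genes on each array, on a log axis, by E2 dose in pM (blue, 5 arrays per dose) and by day of starvation (orange, 3 arrays per day, d0 to d2), with black bars for group means of the linear signals. PDZK1 had a mean signal of 241 at 0 pM and 2139 at 100 pM, and BIK had one of 430 at 0 pM, 21.7 at 100 pM and 574 on day 2.

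Genes of cell division rose almost as whole lists at 100 pM. Of 45 mitosis genes, 44 rose (44 when adjusted over the list alone), with a median log2 change of 1.52 and a camera adjusted p = 1.39e-55. Examples are TACC3 (4.34-fold), CDCA8 (4.28-fold), NEK2 (4.13-fold) and PRC1 (3.65-fold), which act in spindle assembly and chromosome segregation. Of 38 DNA replication genes, 35 rose (38 when adjusted over the list alone), with a median of 1.12 and a camera adjusted p = 4.03e-44, among them RRM2 (4.39-fold), which supplies deoxynucleotides, MCM10 (3.85-fold) and TYMS (3.58-fold). With an estimated correlation the adjusted p was 0.00353 for mitosis and 0.000209 for DNA replication.

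Of 37 known estrogen-induced genes, 22 rose and 1 fell (27 and 1 when adjusted over the list alone), with a median log2 change of 0.73 and an adjusted p = 4.16e-06 with an estimated correlation. The member that fell, STC2, which encodes a secreted glycoprotein, was named after its values were seen and had a log2 change of -1.51 (adjusted p = 4.6e-05). Of 17 known estrogen-repressed genes, 10 fell (10 when adjusted over the list alone), with a median of -0.84 and an adjusted p = 0.000206 with an estimated correlation, among them BLNK (3.25-fold lower). Of 18 FOXO and quiescence genes, 6 fell (7 when adjusted over the list alone), with a median of -0.35 and an adjusted p = 0.00399 with an estimated correlation. These include RBL2, a pocket protein gene that restrains the cell cycle (2.38-fold), CDKN2B (2.35-fold), YPEL5 (2.07-fold) and CCNG2 (2.00-fold).

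Of 17 genes of cholesterol synthesis and uptake, 7 rose and 1 fell at 100 pM (12 and 1 when adjusted over the list alone), with a median log2 change of 0.64 and a camera adjusted p = 1.74e-06. This call was lost with an estimated correlation (adjusted p = 0.0654). ACAT2 rose 2.56-fold, FDPS, a gene of the isoprenoid steps of the pathway, 2.50-fold and IDI1 2.11-fold, while TM7SF2, a sterol reductase gene, fell 2.26-fold. Of 20 luminal epithelial identity genes, 2 rose and 9 fell (2 and 12 when adjusted over the list alone), with a median of -0.42 and a camera adjusted p = 5.19e-05, a call lost with an estimated correlation (adjusted p = 0.0654). With the replicate number also a block, the adjusted p with an estimated correlation was 0.0264 for cholesterol and 0.00129 for luminal genes. SPDEF fell 3.42-fold, ELF3 2.15-fold and CLDN3 1.92-fold. In the ribosome biogenesis list, 1 of 22 genes rose, RRP1B by 1.30-fold (0 when adjusted over the list alone by limma's p), the median was 0.16 and the camera adjusted p was 0.0181. The adjusted p was 0.25 with an estimated correlation (0.101 with the block as well), and the camera adjusted p was 0.0515 without 100 pM replicate 4.

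The other lists were not called at 100 pM, although single members changed. Of 23 hypoxia and glycolysis genes, 4 rose and 2 fell (5 and 4 when adjusted over the list alone, camera adjusted p = 0.392), and ALDOC rose 2.30-fold, ENO2 1.94-fold, PKM 1.58-fold and LDHA 1.56-fold. Of 16 steroid receptor and coregulator genes, 2 rose and 4 fell (2 and 4 adjusted over the list alone, camera adjusted p = 0.415), with NRIP1 1.57-fold higher and RXRA 1.91-fold lower. Of 17 genes of the insulin-like growth factor pathway, 1 rose and 3 fell (1 and 4 adjusted over the list alone, camera adjusted p = 0.486), with IGFBP3 and GRB14 2.08-fold and 1.49-fold lower. Of 15 apoptosis regulators, 2 rose and 3 fell (2 and 3 adjusted over the list alone, camera adjusted p = 0.782), with BCL2L11 1.96-fold higher and BCL2L1 and BAK1 2.12-fold and 1.69-fold lower. Of 15 p53 targets, 1 fell (1 adjusted over the list alone, camera adjusted p = 0.332), the cell cycle inhibitor gene CDKN1A by 1.77-fold.

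Among 20 unfolded protein response genes, 3 rose and 1 fell at 100 pM (3 and 2 adjusted over the list alone, camera adjusted p = 0.124), with PDIA4, SDF2L1 and HYOU1 1.66-fold, 1.39-fold and 1.35-fold higher and HERPUD1 1.70-fold lower. Of 25 interferon response genes, 3 rose (3 adjusted over the list alone, camera adjusted p = 0.486), with ISG20 2.63-fold, IFIT5 1.59-fold and IFITM1 1.44-fold higher. Of 19 immediate early genes, 2 rose and 1 fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.291), with EGR3 2.83-fold and IER3 1.77-fold higher and RHOB 1.79-fold lower. Of 15 fibroblast and endothelial markers, 1 rose and 1 fell (1 and 1 adjusted over the list alone, camera adjusted p = 0.538), COL1A1 by 2.40-fold and COL3A1 by 1.95-fold. Of COL1A1's 3 other probe sets none passed the test with limma and 2 had the opposite sign. In the lists of 11 basal epithelial and 12 immune cell markers, 0 genes passed limma's test, adjusted over all genes or adjusted over the list alone, with camera adjusted p-values of 0.947 and 0.782. The interferon list's median log2 change was -0.04, while its mean was 0.08 and its test pointed up.

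The lower doses were set against 0 pM to show at which concentration the response appears. At 10 pM, the rises included CCN5 (5.32-fold), NPY1R (2.90-fold), PGR (2.39-fold), FDPS (2.00-fold) and OLFM1 (1.86-fold), and the falls CSTA (3.21-fold), IL1R1 (2.84-fold), APOD (2.69-fold), PSCA (2.63-fold) and the sterol transporter gene ABCG1 (2.30-fold). Of OLFM1's 2 other probe sets none passed limma's test and 1 had the opposite sign. FDPS rose from 1972 ± 246 to 3967 ± 463 (SD, n = 5 each, log2 change 1.00 ± 0.12 SE, adjusted p = 0.00022). Of the 10 genes followed throughout, only PGR passed the test. GREB1 had a log2 change of 0.91 ± 0.23 (SE, adjusted p = 0.117) and TFF1 one of 0.85 ± 0.23 (SE, adjusted p = 0.172), and both passed with the replicate number as a block (adjusted p = 0.00308 and 0.016). The other 7 had adjusted p-values of 0.425 or more. In all, 27 genes changed, 18 up and 9 down. The count was 164 with the replicate number as a block, 14 with the pseudocount at the 5th percentile, 9 with array weights, 13 without arrays of actin ratio above 2, and 0 with limma on the 2 groups' arrays alone, where 948 genes had an unadjusted p under 0.05. It was 5, 60, 11 and 15 without 0 pM replicates 1, 2, 3 and 5, and 4, 12 and 8 without 10 pM replicates 2, 3 and 4.

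At 10 pM, 5 lists were called. Of 17 cholesterol genes, 3 rose (10 when adjusted over the list alone), with a median log2 change of 0.61 and an adjusted p = 0.00555 with an estimated correlation; besides FDPS, ACAT2 rose 1.83-fold and HMGCS1 1.71-fold. Of 37 estrogen-induced genes, 5 rose (12 adjusted over the list alone), including PDZK1 by 1.75-fold, with a median of 0.31 and an adjusted p = 0.000153 with an estimated correlation. Of 17 estrogen-repressed genes, 2 fell (3 adjusted over the list alone), with a median of -0.21 and an adjusted p = 0.0139 with an estimated correlation. The medians of mitosis and DNA replication were 0.47 and 0.34, with 1 of 45 and 0 of 38 genes past limma's test (8 and 9 adjusted over the list alone). CCNB2 was the mitosis gene that rose (1.86-fold). Both calls were lost with an estimated correlation (adjusted p = 0.0783 and 0.0515), and were kept when the replicate number was also a block (adjusted p = 0.00278 and 0.0129). The other 14 lists had camera adjusted p-values of 0.153 or more.

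At 30 pM, 503 genes changed, 331 up and 172 down. CCN5 rose 11-fold, NPY1R 4.30-fold, FHL2 and NUDT1 each 4.08-fold and PGR 4.03-fold, and CSTA fell 6.42-fold, BIK 5.97-fold, APOD 4.55-fold, PSCA 3.96-fold and IL1R1 3.22-fold. GREB1 (2.59-fold), TOP2A (2.54-fold), TFF1 (2.38-fold) and IGFBP4 (1.89-fold) had risen. Of GREB1's 2 other probe sets none passed limma's test and 1 had the opposite sign. CCND1 (log2 change 0.48 ± 0.15 SE, adjusted p = 0.066), MKI67 (0.56 ± 0.20 SE, adjusted p = 0.134) and ESR1 (-0.56 ± 0.21 SE, adjusted p = 0.176) did not pass, while with the replicate number as a block all 3 did (adjusted p = 0.0426, 0.0392 and 0.00154 with limma). Without the block, 1 of MKI67's 3 other probe sets passed with the same sign. Of the mitosis genes 39 of 45 rose (44 adjusted over the list alone), of DNA replication 25 of 38 (33), of estrogen-induced genes 16 rose and 1 fell (20 and 1), and of cholesterol genes 6 of 17 rose (12 rose and 1 fell adjusted over the list alone). Of estrogen-repressed genes 5 of 17 fell (7 adjusted over the list alone). These 5 lists were called with an estimated correlation too (adjusted p between 1.72e-06 and 0.00649). The FOXO list, with 1 gene lower (2 adjusted over the list alone), and the luminal list, with 2 lower (2 lower and 1 higher), lost their calls with an estimated correlation (adjusted p = 0.0687 and 0.489, or 0.0467 and 0.0623 with the block as well). The other 12 lists had camera adjusted p-values of 0.178 or more. The count of 503 was 922 with the replicate number as a block, 222 with the 2 groups' arrays alone and 300 without 30 pM replicate 2. The FOXO list was not called without 0 pM replicate 1, 2 or 4 or 30 pM replicate 3 or 5 (camera adjusted p between 0.0531 and 0.123), nor the luminal list without 0 pM replicate 1, 2 or 3 or 30 pM replicate 2, 4 or 5 (between 0.0531 and 0.167).

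At 60 pM, 1167 genes changed, 632 up and 535 down. CCN5 rose 13.1-fold, MYBL1 6.13-fold, NCAPH 5.95-fold, FHL2 5.64-fold and MGP 5.47-fold, and CSTA fell 8.14-fold, BIK 7.53-fold, PSCA 6.46-fold, APOD 5.26-fold and TNS3 4.01-fold. PGR (3.82-fold), GREB1 (2.90-fold), CCND1 (1.90-fold) and MKI67 (1.72-fold) were higher and ESR1 (2.08-fold) was lower, while of its 8 other probe sets none passed the test with limma. Mitosis had 44 of 45 genes higher (44 adjusted over the list alone), DNA replication 34 of 38 (37), estrogen-induced genes 21 higher and 1 lower (29 and 1), cholesterol genes 10 higher and 1 lower (12 and 1), estrogen-repressed genes 7 of 17 lower (9) and FOXO genes 3 of 18 lower (4). All 6 were called with an estimated correlation as well (adjusted p between 1.61e-06 and 0.0235). The luminal list, with 2 genes higher and 5 lower (2 and 9 adjusted over the list alone), lost its call with an estimated correlation (adjusted p = 0.149, or 0.00592 with the block as well). The ribosome biogenesis list had 0 genes past limma's test, adjusted over all genes or adjusted over the list alone and lost its camera call of 0.0495 with an estimated correlation (adjusted p = 0.41, or 0.195 with the block as well), with the replicate number as a block (camera adjusted p = 0.09), and without any of 0 pM replicates 1, 4 and 5 or 60 pM replicates 3, 4 and 5 (camera adjusted p between 0.0604 and 0.236). The other 11 lists had camera adjusted p-values of 0.277 or more. The count of 1167 was 1732 with the replicate number as a block.

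**Figure D2:**
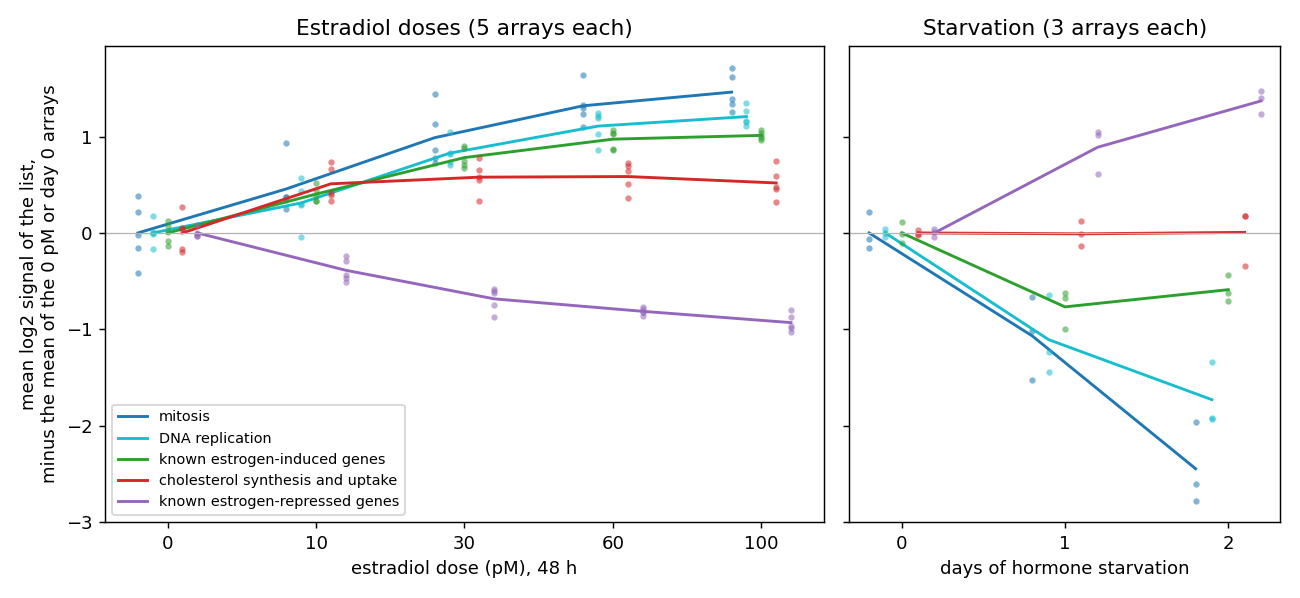
Mean log2 signal of 5 gene lists on each array (points) and per group (lines), relative to the mean of the 0 pM or day 0 arrays, for the E2 doses in pM at equal spacing (left, 5 arrays per dose) and for days of starvation (right, 3 arrays per day). At 100 pM the mean log2 change was 1.46 for mitosis and -0.93 for estrogen-repressed genes, and on day 2 it was -2.45 and 1.37.

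**Figure D3:**
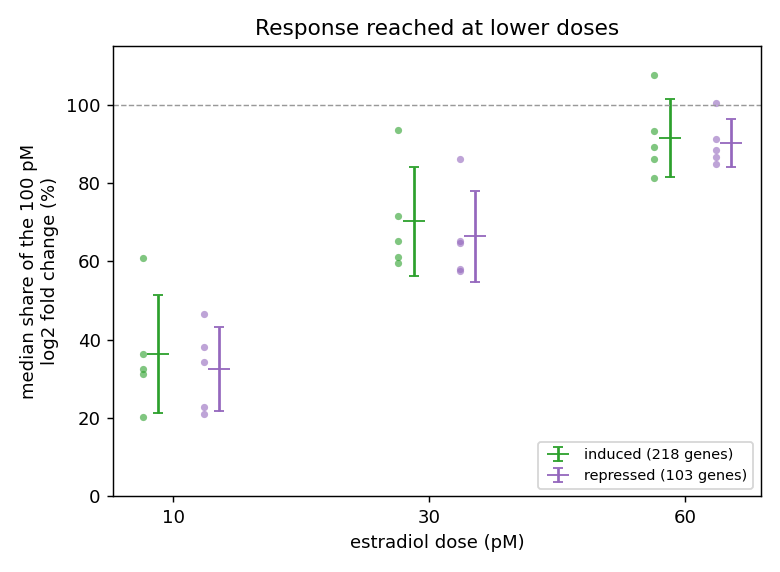
Share of the 100 pM log2 change reached at 10, 30 and 60 pM, in percent, as the median over 218 induced genes (green) and 103 repressed genes (purple). Points are replicate numbers and bars the mean ± SD (n = 5), and the means of induced genes were 36.3%, 70.2% and 91.5%.

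The size of the response at each dose was read as a share of that at 100 pM, over 218 induced and 103 repressed genes. The median share of induced genes was 34.4% at 10 pM, 69.7% at 30 pM and 91.1% at 60 pM. For repressed genes it was 31.2%, 66.3% and 90.5%. Over the replicate numbers the induced genes reached 36.3% ± 15.02, 70.2% ± 13.8 and 91.5% ± 10.0 (SD, n = 5), and the repressed genes 32.5% ± 10.8, 66.4% ± 11.6 and 90.3% ± 6.11. These SDs come from the arrays of the lower dose alone, since the 0 and 100 pM means were held fixed. Replicate 2 had the highest share at each dose in both sets of genes. At 30 pM the induced share exceeded the repressed share by 3.81 ± 2.93 points (SD, n = 5) and was higher in 5 of 5 replicate numbers (exact two-sided sign-flip p = 0.0625, adjusted p = 0.1875). The difference was 3.73 ± 7.95 points at 10 pM (SD, higher in 2 of 5, exact p = 0.5, adjusted p = 0.625) and 1.23 ± 4.63 at 60 pM (SD, higher in 2 of 5, exact p = 0.625, adjusted p = 0.625). The smallest p that 5 pairs allow is 0.0625, so no difference could pass this test. All shares use the same 0 pM arrays in numerator and denominator. With 0 pM replicates 1 and 2 for the lower dose and 3 to 5 for 100 pM, the induced genes' share was 53.7% at 30 pM and 76.9% at 60 pM. The reverse split was not run for these genes, so the values also hold any difference between these 0 pM arrays. For 765 induced genes outside the cholesterol list, the share at 10 pM was 30.9% with this split and 41% with its reverse.

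Neighbouring doses were compared to show where the response still grew. Between 10 and 30 pM, 4 genes changed. PDZK1 rose 2.04-fold (log2 change 1.03 ± 0.17 SE, adjusted p = 0.0235), OLFM1 1.88-fold and the mitotic kinesin gene KIF20A 1.64-fold. BIK, named after its values were seen because 1 array at 30 pM overlapped those at 10 pM, fell by 1.57 on the log2 scale (adjusted p = 0.0235). The 10 genes followed throughout did not pass, and IGFBP4 (log2 change 0.70 ± 0.16 SE, adjusted p = 0.134) and TOP2A (0.87 ± 0.21 SE, adjusted p = 0.148) had the lowest adjusted p-values. With the replicate number as a block both passed (adjusted p = 0.0253 and 0.0126 with limma). The count was 96 with the replicate number as a block. It was 8 with the pseudocount at the 40th percentile, with the mean of a gene's probe sets, with trend and robust settings or without 30 pM replicate 4, 7 with the filter or with array weights, 2 with every probe set by itself and 24 without 10 pM replicate 2. It was 0 with limma without 10 pM replicates 1, 3 or 5 or 30 pM replicates 2 or 5 (634, 641, 924, 614 and 749 genes at an unadjusted p under 0.05), in the 2 groups' arrays alone (783), and without arrays of actin ratio above 2 or 1.5 (668 and 666).

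From 30 to 60 pM and from 60 to 100 pM, 0 genes passed limma's test, with 478 and 215 genes at an unadjusted p under 0.05. With the replicate number as a block the counts were also 0 (838 and 365 at an unadjusted p under 0.05), and without 30 pM replicate 2 the first was 1. The 10 genes followed throughout had adjusted p-values of 1 in both comparisons. PGR differed by -0.07 ± 0.21 from 30 to 60 pM and by -0.02 ± 0.21 from 60 to 100 pM (log2 change ± SE), TFF1 by -0.19 ± 0.23 and 0.07 ± 0.23, and GREB1 by 0.16 ± 0.23 and 0.19 ± 0.23. CCND1 (0.44 ± 0.15) and ESR1 (-0.50 ± 0.21) had larger values from 30 to 60 pM, which did not pass the test. These intervals leave room for changes of the size of their errors, and do not show that the doses act alike.

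Over the wider step from 10 to 100 pM, 623 genes changed, 354 up and 269 down. CFAP70 rose 5.83-fold, PDZK1 4.57-fold, MYBL1 4.56-fold, NRGN 4.35-fold and FHL2 4.03-fold, and BIK fell 4.13-fold, SIL1 3.41-fold, BLNK 3.20-fold, EFEMP1 2.92-fold and GPER1, the gene of a G protein-coupled estrogen receptor, 2.72-fold. TOP2A (2.58-fold), IGFBP4 (2.26-fold), CCND1 (1.89-fold), GREB1 (1.75-fold) and MKI67 (1.61-fold) rose and ESR1 fell 1.72-fold, while of its 8 other probe sets none passed the test with limma and 3 had the opposite sign. GREB1's 2 other probe sets did not pass either, and 1 had the opposite sign. PGR had a log2 change of 0.66 ± 0.21 (SE, adjusted p = 0.0758, or 0.0353 with the replicate number as a block) and TFF1 one of 0.29 ± 0.23 (SE, adjusted p = 0.633), while MYC and CXCL12 had adjusted p-values of 0.925 and 0.933. The count was 1063 with the replicate number as a block, 377 and 390 without arrays of actin ratio above 2 or 1.5, and 392 without 10 pM replicate 1. Over all 5 doses, 992 genes passed the moderated F test, and 1553 did with the block.

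The starvation experiment followed cells after their transfer to stripped medium. After 1 day, 11 of 37 known estrogen-induced genes and 21 of 38 DNA replication genes were lower than on day 0, though the calls of both lists were lost with an estimated correlation (adjusted p = 0.0535 and 0.109). CCN5 fell from 1342 ± 273 to 159 ± 88.6 (SD, n = 3 each, 7.75-fold, adjusted p = 0.0126), CDC25A, a phosphatase gene of the cell cycle, fell 5.24-fold, FHL2 4.56-fold, OLFM1 4.53-fold and TEDC2 4.50-fold. Of OLFM1's 2 other probe sets, 1 also fell and 1 had the opposite sign. SELENOP rose 5.68-fold, GPER1 5.46-fold, BLNK 5.11-fold, the sterol transporter gene ABCG1 5.03-fold and the histone gene H2BC5 4.91-fold. IGFBP4 fell 3.28-fold and MKI67 1.94-fold. CCND1 (log2 change -0.99 ± 0.24 SE, adjusted p = 0.0529), GREB1 (-0.96 ± 0.24, adjusted p = 0.057), ESR1 (0.62 ± 0.18, adjusted p = 0.0943), TOP2A (-1.19 ± 0.36, adjusted p = 0.105), MYC (0.69 ± 0.21, adjusted p = 0.108), PGR (-1.01 ± 0.49, adjusted p = 0.306), TFF1 (-0.26 ± 0.27, adjusted p = 0.657) and CXCL12 (-0.20 ± 0.24, adjusted p = 0.725) did not pass. TOP2A and CXCL12 each have 1 other probe set, which passed limma's test with the same sign. In all, 489 genes changed, 257 up and 232 down, but fewer rose than fell with quantile normalization (220 up, 253 down), with the pseudocount at the 40th percentile (388 up, 389 down) and without day 1 replicate 1 (177 up, 219 down). The count was between 251 (pseudocount at the 5th percentile) and 933 (array weights) over the alternatives, with 391 when the replicate number was a block, and was 169, 67 and 53 without day 0 replicates 1, 2 and 3 and 43 without day 1 replicate 2 or replicate 3.

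Of the lists on day 1, DNA replication had 21 of 38 genes lower (32 adjusted over the list alone), mitosis 12 of 45 (40), estrogen-induced genes 11 of 37 (19 lower and 1 higher) and ribosome biogenesis 2 of 22 (2), with median log2 changes of -1.08, -1.06, -0.61 and -0.37. FOXO and quiescence genes had 8 of 18 higher (11 higher and 1 lower adjusted over the list alone) and estrogen-repressed genes 7 of 17 (10), with medians of 0.88 and 0.78. The interferon list had 1 gene higher, IRF7, and 1 lower, ISG20, with a median of 0.39. The camera call of all 7 was lost with an estimated correlation (adjusted p = 0.109, 0.16, 0.0535, 0.0535, 0.0535, 0.0729 and 0.192, in this order). The interferon call was also lost without day 0 replicate 3 or day 1 replicate 3 (camera adjusted p = 0.0643 and 0.0827). The other 12 lists had camera adjusted p-values of 0.0681 or more. Members past the test included CDC6 (3.42-fold lower), GINS4 (3.56-fold lower), MCM10 (3.55-fold lower), CCNA2 (3.04-fold lower), PNRC1 (3.43-fold higher) and CCNG2 (3.33-fold higher). GINS4 and IRF7 did not pass with the replicate number as a block (adjusted p = 0.0552 and 0.0628 with limma).

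After 2 days of starvation, 45 of 45 mitosis genes and 36 of 38 DNA replication genes were lower than on day 0 and 9 of 18 FOXO and quiescence genes were higher, though the calls of these lists were lost with an estimated correlation (adjusted p = 0.089, 0.089 and 0.0623). The mitotic gene TACC3 fell from 1136 ± 360 to 52.4 ± 24.6 (SD, n = 3 each, log2 change -3.75 ± 0.31 SE, adjusted p = 0.000319). CCN5 fell 11.6-fold, RRM2 9.27-fold, NUDT1 9.21-fold, CDC45 9.17-fold, FOXM1, a transcription factor gene of the mitotic program, 8.69-fold, PRC1 8.60-fold, KIF23 and CEP55 each 8.37-fold and AURKB 8.24-fold. BIK rose from 13.6 ± 1.11 to 574 ± 148 (log2 change 3.66 ± 0.40 SE, adjusted p = 0.000802). SELENOP rose 12.5-fold, CSTA 10.2-fold, PSCA 8.18-fold, IGFBP5 7.91-fold, GPC5 6.95-fold, BLNK 6.88-fold, GPER1 6.58-fold, IL1R1 6.00-fold and PLEKHF1 5.97-fold. ESR1 rose 2.20-fold, while of its 8 other probe sets none passed the test with limma. TOP2A fell 6.52-fold, MKI67 3.47-fold, IGFBP4 1.96-fold and CCND1 1.95-fold. GREB1 (log2 change -0.59 ± 0.24 SE, adjusted p = 0.153), TFF1 (-0.64 ± 0.27, adjusted p = 0.158), PGR (-1.22 ± 0.49, adjusted p = 0.146), MYC (0.55 ± 0.21, adjusted p = 0.131) and CXCL12 (-0.36 ± 0.24, adjusted p = 0.395) did not pass. In all, 1558 genes changed, 849 up and 709 down, and 726 by 2-fold or more. The beta-actin 3'/5' ratio was 1.93 ± 1.03 on day 2 against 1.02 ± 0.0231 on day 0, and the count was 225 without arrays of ratio above 1.5, which leaves 1 array on day 2, and 603 with the log2 ratio as a covariate. The 1558 genes had a median size of the log2 change, in either direction, of 0.969 (median SE 0.196), which was 0.869 (0.255) without these arrays and 0.887 (0.229) with the covariate, with 1558 of the same sign in both. The genes were chosen on the same arrays, so kept signs follow largely from that choice and do not bear on RNA integrity. The count was 1456 with the replicate number as a block, 930 without day 0 replicate 2, 923 without day 0 replicate 3 and 939 without day 2 replicate 3.

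On day 2 all 45 mitosis genes were lower (45 adjusted over the list alone), with a median log2 change of -2.41, as were 36 of 38 DNA replication genes (36), with a median of -1.65, in the group whose actin ratio was also higher. Both calls were lost with an estimated correlation (adjusted p = 0.089 for each). CHAF1B fell 7.01-fold and GINS2 7.49-fold. Of 18 FOXO and quiescence genes, 9 were higher (14), with a median of 0.83 (adjusted p = 0.0623 with an estimated correlation), among them YPEL5 (5.79-fold), RBL2 (4.59-fold), PNRC1 (4.42-fold) and CCNG2 (3.06-fold). Of 17 estrogen-repressed genes, 10 were higher (13), with a median of 0.94 (adjusted p = 0.0623 with an estimated correlation). Of 37 estrogen-induced genes, 2 were higher and 11 lower (2 and 13), with a median of -0.45 (adjusted p = 0.151 with an estimated correlation). CTSD and MYBL1 fell 4.56-fold and 4.13-fold, and the 2 that rose, named after their values were seen, were STC2 (log2 change 1.74) and MYB (1.12). Of 22 ribosome biogenesis genes, 5 were lower (6), with a median of -0.34 (adjusted p = 0.0691 with an estimated correlation), among them RRP9, MYBBP1A and NOLC1 (1.99-fold, 1.83-fold and 1.63-fold). Of 15 p53 targets, 5 were higher (6), with a median of 0.27 (adjusted p = 0.108 with an estimated correlation), among them CDKN1A (4.93-fold), GDF15 (2.50-fold) and CCNG1 (2.09-fold). Of 16 steroid receptors and coregulators, 5 were higher (5), with a median of 0.35 (adjusted p = 0.151 with an estimated correlation), among them RXRA (2.31-fold), NCOA1 (2.16-fold) and TRIM24 (1.91-fold). Without day 2 replicate 1 the p53 and receptor lists were not called (camera adjusted p = 0.0557 and 0.0596).

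The remaining lists were not called on day 2. Of 17 cholesterol genes, 2 rose and 3 fell (3 and 4 adjusted over the list alone, camera adjusted p = 0.756), with ACAT2, EBP and FDPS 2.19-fold, 2.25-fold and 1.83-fold lower and TM7SF2 2.59-fold higher. Of EBP's 2 other probe sets, 1 also fell and 1 had the opposite sign. Of 17 insulin-like growth factor genes, 5 rose and 2 fell (6 and 2, camera adjusted p = 0.0613), with IRS2 2.63-fold and GRB14 2.01-fold higher and IGFBP6 2.17-fold lower. Of 20 luminal genes, 4 rose and 1 fell (7 and 2, camera adjusted p = 0.0613), with SPDEF 3.04-fold and ERBB3 2.69-fold higher and TFF3 2.92-fold lower. Of 15 apoptosis regulators, 5 rose and 1 fell (6 and 2, camera adjusted p = 0.315), with TNFRSF10B 1.78-fold and BCL2 1.65-fold higher and BID 2.16-fold lower. Of the other probe sets of TNFRSF10B (2) and BCL2 (3), none passed limma's test and 1 of each gene had the opposite sign. Of 23 hypoxia and glycolysis genes, 3 rose and 3 fell (4 and 8, camera adjusted p = 0.282), with MXI1 2.86-fold and KDM3A 2.14-fold higher and LDHA 2.09-fold and PKM 1.92-fold lower. Of 20 unfolded protein response genes, 4 rose and 2 fell (4 and 3, camera adjusted p = 0.602), with DDIT4 3.60-fold and HERPUD1 1.79-fold higher and HSP90B1 3.49-fold and PDIA4 2.27-fold lower. Of 25 interferon genes, 2 rose and 1 fell (2 and 1, camera adjusted p = 0.756), with IFI6 2.63-fold and SP110 1.62-fold higher and ISG20 1.90-fold lower. Of 19 immediate early genes, 1 rose and 1 fell (1 and 1, camera adjusted p = 0.756), JUNB by 2.10-fold and IER3 by 2.09-fold. CAV1 (2.46-fold) was the 1 of 11 basal markers and PECAM1 (1.71-fold) the 1 of 15 fibroblast and endothelial markers that rose (1 and 1, camera adjusted p = 0.316 and 0.938), and 0 of 12 immune markers passed limma's test, adjusted over all genes or adjusted over the list alone (camera adjusted p = 0.992). Of PECAM1's 2 other probe sets none passed limma's test and 1 had the opposite sign.

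Between day 1 and day 2, 15 genes changed, 7 up and 8 down. NUDT1 fell from 250 ± 89.8 to 15.03 ± 3.97 (SD, n = 3 each, 5.66-fold, adjusted p = 0.0118), and CENPE, TACC3, CDC20 and CCNB2, genes of chromosome segregation and mitotic entry and exit, fell 5.30-fold, 5.23-fold, 3.49-fold and 2.94-fold. TMEM127 rose 6.08-fold, SCUBE2 5.68-fold, CSTA 4.62-fold, and STC2 3.67-fold, and CYP1A1, a gene of xenobiotic metabolism, rose by 1.81 on the log2 scale. Of these, CENPE, TACC3, CDC20 and SCUBE2 did not pass with the replicate number as a block (adjusted p = 0.0537 for each with limma). None of the 10 genes followed throughout passed, with adjusted p-values of 0.167 (TOP2A) or more. In this comparison the actin ratio was 1.93 ± 1.03 on day 2 against 1.04 ± 0.0786 on day 1. The count was 0 with limma without arrays of ratio above 1.5 or with the log2 ratio as a covariate (624 and 771 genes at an unadjusted p under 0.05). The median size of the 15 changes was 1.81 (median SE 0.245), against 1.71 (0.318) without these arrays and 1.79 (0.263) with the covariate, with 15 of the same sign in both. These genes too were chosen on the same arrays, so kept signs follow largely from that choice. The count was 3 without arrays of ratio above 2, 0 with limma on the 2 groups' arrays alone (1218 genes at an unadjusted p under 0.05), and between 3 and 167 over the other alternatives, with 11 when the replicate number was a block. It was 2 and 1 without day 1 replicates 1 and 3, 74 and 3 without day 2 replicates 1 and 2, and 0 with limma without day 2 replicate 3 (1117 genes at an unadjusted p under 0.05).

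The 2 experiments, which share no arrays, were then set against each other to ask whether genes that respond to added E2 move the other way when hormone is withdrawn. BIK, CSTA, APOD, PSCA and IL1R1 fell with 100 pM E2 and rose on day 2, and CCN5, OLFM1, CDC45, NUDT1 and NCAPH did the reverse. Of the genes called in both comparisons, 442 rose with E2 and fell on day 2 and 395 fell with E2 and rose on day 2, 837 in all, where independent lists of these sizes would share 94.9. Only 4 genes changed in the same direction, against 95.8 for independent lists. Of the 1558 genes that changed on day 2, 1462 (93.8%) had the opposite sign at 100 pM. Across the 11963 genes, which are not independent replicates, the log2 changes had a Pearson r of -0.643, a Spearman rho of -0.494 and a covariance of -0.15. Without arrays of actin ratio above 1.5 the opposite calls numbered 171, and with the log2 ratio as a covariate 459.

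**Figure D4:**
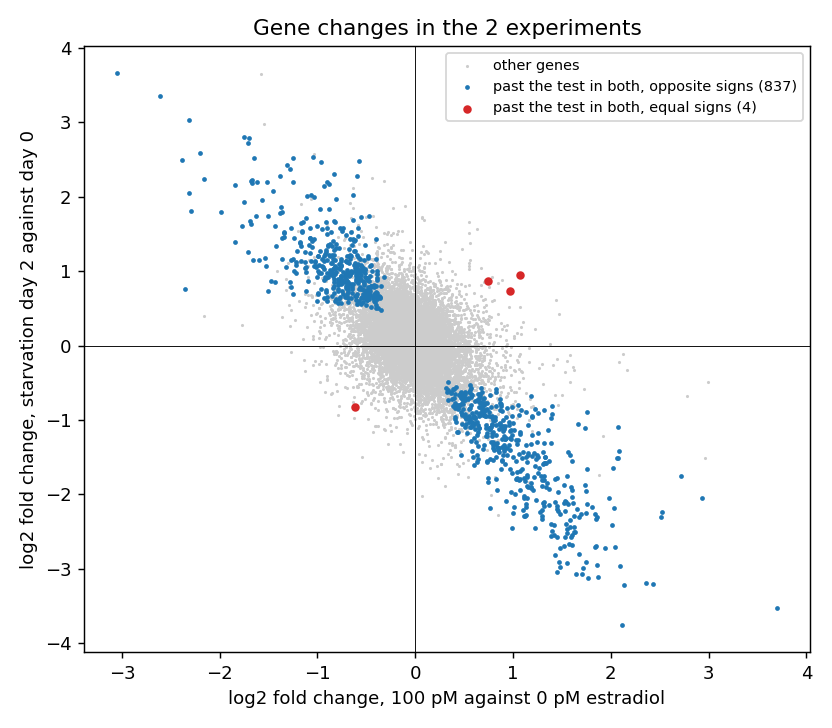
Log2 fold change at 100 against 0 pM E2 (horizontal) and on day 2 against day 0 of starvation (vertical) for each of 11963 genes. Blue points are the 837 genes that passed the test in both with opposite signs, red points the 4 with equal signs, and grey points all others.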

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

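All regroupings of arrays and all tests of explanations below, except that of RNA integrity, were chosen after the results they concern were seen. The bounds of the test of RNA integrity by slopes were fixed before its own result, though after the changes on day 2 were known. It replaced earlier tests, by signs at 100 pM and by replicate 1 alone, which could not decide. The bound for the shared 0 pM arrays was tightened, and the search for arrays far from their group was widened from a smaller set of genes to 75, once a first result was known.

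On day 2 of starvation, where 1558 genes differed from day 0, the actin 3'/5' ratio was high in replicates 2 and 3 (2.96 and 1.95) and 0.902 in replicate 1, so RNA integrity may have contributed. As a test, the slope of each gene on the log2 ratio was taken within groups of the estradiol experiment, with the replicate number in the model. These estradiol slopes had a Pearson r of 0.268, across genes, which are not independent replicates, with slopes within starvation groups, taken without the number. Against integrity as the main cause, these slopes predicted a median of 4.46% of the change of the 1558 genes and 4.35% for the 15 genes that differed between day 1 and day 2, and between 3.65% and 6.05% and between 2.82% and 7.39% without single arrays of high ratio. With the ratio as a covariate the median size of the log2 change, in either direction, of the 1558 genes was 0.887 (median SE 0.229) against 0.969 (0.196), with 567 past the test, and that of the 15 was 1.79 (SE 0.263) against 1.81 (0.245), with 0 past limma's test (771 of all genes at an unadjusted p under 0.05). Both sets of genes were chosen on the same arrays, which favours kept sizes. The slopes predicted the sign of the change in 62.6% of the 1558 and 73.3% of the 15 genes and the errors grew in both cases, so a smaller share of integrity, or one that the weakly related slopes miss, stays open.

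The 7 cholesterol genes that rose at 100 pM had reached a median of 87.8% of that rise at 10 pM, against 35.8% for induced genes in general. In 10000 draws of induced genes of like signal the highest median was 80%. The genes were drawn independently, while those of the list are correlated (estimated correlation 0.235). The draws therefore cannot decide on brightness as the whole cause. A response to lower estradiol than other induced genes need is a candidate explanation, as the list's change at 10 pM exceeded the typical share (adjusted p = 0.0266 with an estimated correlation). The 0 pM arrays common to both values cannot be told apart from it: with different 0 pM arrays for 10 and 100 pM the share was 50.1% or 79.5%, against 30.9% and 41% for other induced genes. The draws, the bounds and the genes were chosen on the same data, so this is a hypothesis.

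Arrays of the estradiol experiment with the same replicate number shared deviations from their group means, with a median correlation of 0.172 against -0.0518 between different numbers. The signal of a control RNA added at hybridisation followed the number, with 91.9% of its variance between numbers (permutation p = 1e-05, the smallest that 1e+05 permutations can give), which is consistent with hybridisation batches that each held every dose. Cultures grown together under one number could give the same correlation of 0.172 and cannot be told apart from such batches, because both would follow the number. The control RNA's signals overlapped between numbers 1 (3284.6 to 5079.2) and 2 (4262.1 to 7124.7). They also overlapped between 3 (8572.1 to 11756) and 4 (10638 to 19135) and between 4 and 5 (13809 to 19483). A separate batch for each number was therefore not shown. Counts with the number as a block stand in the report.

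Arrays were regrouped at random, with 100 regroupings including the real one for 5 against 5. For 10, 30, 60 and 100 against 0 pM, 2, 1, 1 and 1 of them gave as many genes as the real 27, 503, 1167 and 1464, and the highest others were 48, 32, 47 and 5. Regrouped without regard to the replicate number, these reached a share under 0.05. So did 30 against 10 pM (3 regroupings, real 4, highest other 4) and 100 against 10 pM (1, real 623, highest other 35). The F test (1, real 992, highest other 119) did too. The opposite calls (1, real 837, highest other 1) cannot be judged this way. Every other starvation regrouping called 0 genes by limma, so most regroupings gave 0 opposite calls by construction. The 48 came from exchanging 0 pM replicate 2 with 10 pM replicate 5. For 60 against 30 and 100 against 60 pM the real count was 0 by limma (478 and 215 genes at an unadjusted p under 0.05). Each of the 100 regroupings gives at least as many by construction, with highest others of 1 and 2, which says nothing about chance. The starvation comparisons have 10 regroupings each, too few for a share under 0.05, with real counts of 489, 1558 and 15 and a highest other of 0 by limma, with 1 regrouping of 10 as high in each case. These regroupings ignored the replicate number, whose arrays shared deviations, so they do not settle the part of chance. In any regrouping, swaps within a number included, real changes also add to the spread within groups. Responding genes then lose their calls, which lowers the other counts by construction. Swaps within a number were run only for the doses against 0 pM. When labels were swapped only within a number, with the number as a block, 16 regroupings were possible for each dose, too few for a share under 0.05, with real counts of 164, 922, 1732 and 2067 at 10, 30, 60 and 100 pM and highest others of 1, 1, 4 and 8.

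The number of lists called by camera was no guide to the real grouping. At 10, 30, 60 and 100 pM, 7, 5, 4 and 8 of 100 regroupings called as many lists as the real 5, 7, 8 and 8, and the highest others were 6, 7, 8 and 9, so a share under 0.05 was reached at 60 pM alone. The 16 regroupings within replicate numbers are too few for such a share, with real numbers of 5, 7, 7 and 8 lists and highest others of 5, 8, 8 and 9. On day 1 and day 2, 3 of 10 regroupings in each called as many as the real 7 and 8, with highest others of 8 and 10. The size of each list's median was therefore also compared, again ignoring the number. At 100 pM, mitosis had a median log2 change of 1.52 against at most 1.14 in size in other regroupings, DNA replication 1.12 against 0.8 and estrogen-repressed genes -0.84 against 0.62, while ribosome biogenesis had 0.16 against 0.19. At 10 pM, cholesterol genes had 0.61 against 0.57 and estrogen-induced genes 0.313 against 0.304. Some of the other called lists were matched or exceeded by another regrouping. At 10 pM these were mitosis (0.47 against 0.50), DNA replication (0.345 against 0.347) and estrogen-repressed genes (-0.21 against 0.28, with 7 of 100 as far from 0). They also were FOXO (-0.2 against 0.205) and luminal genes (-0.215 against 0.257) at 30 pM, ribosome biogenesis at 60 pM (0.14 against 0.19), FOXO genes at 100 pM (-0.354 against 0.372), and p53 targets (0.275 against 0.346) and steroid receptors (0.348 against 0.355) on day 2.

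In groups of 5 arrays, 14 of 171 sets of values had an array far from the others, where chance gives about 8.55. At 100 pM, replicate 3 had a TFF1 signal of 38900 (others 17280 to 20000), a PRSS23 signal of 1867 (3115 to 3456), an OLFM1 signal of 2976 (3834 to 4181), an ELF3 signal of 806.4 (448.5 to 541.7), a HERPUD1 signal of 996.8 (558 to 672.6) and an actin ratio of 2.595 (0.9859 to 1.018). Replicate 2 at 100 pM had an ALDOC signal of 526.7 (807.4 to 875) and replicate 1 a BLNK signal of 317.5 (153.8 to 195.6). At 0 pM, replicate 2 had a CLDN3 signal of 2042 (3465 to 3909) and a PDIA4 signal of 496 (1080 to 1189), and replicate 3 an NUDT1 signal of 106.5 (13.6 to 34). At 10 pM, replicate 3 had an actin ratio of 2.867 (0.931 to 1.246) and a GAPDH ratio of 1.312 (0.9215 to 1.009). The repressed genes' share at 30 pM was 86.14% in replicate 2 (57.64% to 65.31% in the others).

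The change from day 0 differed between day 2 and day 1 in 15 genes, by the test of that difference. Among 3150 probe sets without a single gene symbol, which stand in no comparison, 191 passed the test at 100 against 0 pM (80 up, 111 down) and 189 on day 2 against day 0 (111 up, 78 down).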

How the results depend on the processing

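Of the genes named by the rule, counted in each comparison where they were called, and of the called lists, none reversed its direction under the alternatives run on them, but the balance of rises and falls did in 2 comparisons. On day 1 it was 257 up and 232 down, against 220 and 253 with quantile normalization, 388 and 389 with the pseudocount at the 40th percentile and 177 and 219 without day 1 replicate 1. For day 2 against day 1 it was 7 and 8, against 6 and 5 with the replicate number as a block and 2 and 1 with every probe set by itself, without arrays of actin ratio above 2 or without day 2 replicate 2. Over the alternatives that keep all replicates or drop arrays by actin ratio, 4294 of 4659 values of these named genes and 646 of 688 of called lists stayed past the threshold, and 365 and 42 did not. Without single arrays, 2290 of 2828 and 348 of 370 did. These genes and lists had been called on the same arrays, so kept directions and calls follow in part from that choice. Of values not called, 44 of 1050 for named genes and 23 of 1136 for lists were past it. Of the lists' lost calls, 24 came with the estimated correlation, which kept 19 of 43. With fry, which does not compare a list with other genes, 41 of 43 called lists passed, as did 9 of 71 lists that were not called. Scaling to a common trimmed mean moved almost nothing, since the arrays were already scaled, and says nothing about stability. Other called genes were not followed singly, and named genes, list tests and response shares were not run with every probe set by itself. By construction the pseudocount shrinks fold changes of genes whose signal is near it, so signal over background limits these. Except where fewer genes or arrays were used, the cause of a move was not tested.

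With the replicate number as a block, counts were 164 (10 against 0 pM), 922 (30 against 0), 96 (30 against 10), 1063 (100 against 10) and 1553 (F test). Arrays of one number had correlated deviations above 0.1 in 41 of 50 pairs in the estradiol experiment and 1 of 9 in the starvation experiment, where 9 of 9 arrays still correlated best with their own number (median 0.0869 within and -0.043 between numbers). The rule for blocking, that all pairs exceed it, was not met, and this check was seen together with the blocked counts. With only the groups compared, counts were 0 by limma for 10 against 0 pM, 30 against 10 pM and day 2 against day 1 (948, 783 and 1218 genes at an unadjusted p under 0.05), and 222 for 30 against 0 pM. With the pseudocount at the 5th percentile they were 14 (10 against 0 pM), 251 (day 1) and 4 (day 2 against day 1), and at the 40th 8 (30 against 10 pM), 777 and 26. With the dim-gene filter they were 7 (30 against 10 pM), 800 (day 1) and 51 (day 2 against day 1), with trend and robust settings 8, 800 and 88, and with array weights 9 (10 against 0 pM), 7 (30 against 10 pM) and 933 (day 1). All 34 arrays in one fit gave 898 (day 1) and 167 (day 2 against day 1). For 30 against 10 pM the mean of probe sets gave 8 and every probe set by itself 2, and for day 2 against day 1 the latter gave 3.

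The alternatives on RNA integrity were chosen after seeing the data. Without arrays of actin ratio above 2, counts were 13 (10 against 0 pM), 377 (100 against 10 pM), 3 (day 2 against day 1) and 0 by limma (30 against 10 pM, 668 at an unadjusted p under 0.05). Without those above 1.5, they were 390 (100 against 10 pM), 225 (day 2), 171 (opposite calls), and 0 by limma for 30 against 10 pM and day 2 against day 1 (666 and 624 at an unadjusted p under 0.05); day 2 then has 1 array, assumed to vary like the other groups. With the ratio as a covariate they were 603 (day 2), 459 (opposite calls) and 0 by limma (day 2 against day 1, 771 at an unadjusted p under 0.05). With separate 0 pM arrays, split in 1 direction only, the induced genes' share was 53.74% at 30 pM and 76.88% at 60 pM. The repressed genes' share at 60 pM was 84.14% with genes chosen on replicates 1 to 3.

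Without single arrays, counts ranged from 4 (10 pM replicate 2) to 60 (0 pM replicate 2) for 10 against 0 pM, where 0 pM replicates 1, 3 and 5 gave 5, 11 and 15 and 10 pM replicates 3 and 4 gave 12 and 8. They ranged from 300 (30 pM replicate 2) to 498 for 30 against 0 pM, 827 to 1130 for 60 against 0, 1226 to 1456 for 100 against 0, 392 (10 pM replicate 1) to 596 for 100 against 10, and 858 to 1016 for the F test. For 30 against 10 pM the range was 0 by limma (10 pM replicates 1, 3 and 5 and 30 pM replicates 2 and 5, with 634, 641, 924, 614 and 749 at an unadjusted p under 0.05) to 24 (10 pM replicate 2), with 8 for 30 pM replicate 4. It was 0 to 1 (30 pM replicate 2) for 60 against 30 and 0 to 0 for 100 against 60 pM. Day 1 ranged from 43 (day 1 replicates 2 and 3) to 396, with 169, 67 and 53 for day 0 replicates 1, 2 and 3. Day 2 ranged from 923 (day 0 replicate 3) to 1563, with 930 and 939 for day 0 replicate 2 and day 2 replicate 3. Day 2 against day 1 ranged from 0 by limma (day 2 replicate 3, 1117 at an unadjusted p under 0.05) to 74 (day 2 replicate 1), with 2, 1 and 3 for day 1 replicates 1 and 3 and day 2 replicate 2. Opposite calls ranged from 595 to 801. Induced genes' shares ranged from 26.96% to 38.24% at 10 pM, 63.99% to 72.5% at 30 pM and 87.62% to 93.67% at 60 pM, and repressed genes' from 27.03% to 34.3%, 59.62% to 71.12% and 87.27% to 92.67%.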

Other observations

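The genes below were chosen after their values were seen, as was the question of which genes moved alike in both experiments. Of the genes that passed the test in both, 4 changed in the same direction with 100 pM E2 and after 2 days of starvation. SCD, which encodes a fatty acid desaturase, had a log2 change of 0.97 (adjusted p = 0.005) with E2 and 0.74 (adjusted p = 0.0463) on day 2. CAV2, a caveolin gene, had changes of 0.75 and 0.87 (adjusted p = 0.021 and 0.0218), and SLC26A2, a sulfate transporter gene, had changes of 1.07 and 0.95 (adjusted p = 0.00578 and 0.0152). ST6GALNAC4, a sialyltransferase gene, was lower in both, by -0.62 and -0.83 (adjusted p = 0.0232 and 0.0175). Independent lists of these sizes would share 95.8 genes with equal signs, and no explanation was tested. The threshold of 0.05 admits some false calls, and these were not excluded for the 4 genes.

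Among the 7 cholesterol genes that rose at 100 pM, the share of that rise reached at 10 pM was 124% for HMGCS1, 97.6% for IDI1, 93.1% for MSMO1, 87.8% for SQLE, 75.5% for FDPS, 64.1% for ACAT2 and 61.2% for DHCR7. On day 2 of starvation FDPS and ACAT2 were lower, with log2 changes of -0.87 and -1.13 (adjusted p = 0.01 and 0.0061). HMGCS1 (0.06), SQLE (-0.05), IDI1 (0.52), MSMO1 (0.32) and DHCR7 (-0.62) did not pass (adjusted p between 0.078 and 0.902).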
